A study of Mus musculus with 106 samples.

How the data were processed

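Single cells were taken from mouse embryos of the C57BL/6 strain between the pre-streak stage and embryonic day 8.25. Per the labels' protocols, fragments holding PGCs or their precursors were dissected out and dissociated with trypsin and EDTA, cells were picked at random, and the lysate of each cell was reverse transcribed and its cDNA amplified by PCR without purification. Biotin-labelled cRNA was made from it by the one-cycle Affymetrix protocol, per the labels, so each array carries 1 cell. Groups were chosen by transcripts in the amplified cDNA, per the labels: Oct4 (Pou5f1) and T for pre-streak epiblast, Blimp1 (Prdm1) and Oct4 for precursors, Blimp1 and stella (Dppa3) for PGCs, Blimp1, Oct4 and Hoxb1 for Blimp1+ Hoxb1+ cells, Oct4 and Hoxb1 without Blimp1 for posterior mesoderm, and the transcript of the Blimp1-null allele with Oct4 for knockout cells. Genes used in this way are not findings between groups chosen by them. Screening by Blimp1 and fragilis (Ifitm3) is also named in the labels.

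The deposited values are linear array intensity, 1 value per probe set and cell, made by the authors with MAS5, per the submitters' processing notes; the version, the target of any scaling and the treatment of low values are not given in the sources used here. In the files, 15.3% of values stood at the lowest value of 1, means trimmed by 2% ranged from 131 to 207 between cells, 1 value was missing and 0 pairs of cells were identical. Amplification from 1 cell loses rare transcripts at random, so a low value does not show that a transcript was absent, and the number of arrays limits the precision. The array had 45101 probe sets, of which 64 were controls; 34945 had 1 gene symbol in the platform annotation, 932 several and 9160 were unnamed here, and only those with 1 symbol were used, giving 18193 genes. Symbols were compared with the gene table of assembly GRCm38.p6, and 0 needed updating. No coordinates were used.

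Background was taken from 126 probe sets of olfactory, vomeronasal and taste receptor and hair keratin-associated genes (symbols starting Olfr, Vmn, V1r, V2r, Tas2r or Krtap). The floor was the median over cells of their 90th percentile, a signal of 70.2 (6.13 in log2), and lower values were raised to it before taking log2. A gene was called detected in a cell when its signal exceeded the 95th percentile of these probe sets in that cell, which lay between 82.7 and 165 (median 120). For genes with several probe sets, the one with the highest mean log2 signal over all cells was used. Averaging the probe sets was an alternative, given below as a count of the named genes that moved and not gene by gene.

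No embryo, litter or pool is named in the labels, so each group counted as 1 sample and no test, p-value or standard error was computed. Each gene is given as the difference of group means of floored log2 signal, with the SD over cells, and the number of cells in which it was detected, with exact (Clopper-Pearson) 95% intervals where given, which cover counting error only. A fold is given only as a lower bound, where the dimmer group had 0 cells above the detection limit: the mean of the brighter group over the mean, in the dimmer group, of the higher of each cell's detection limit and its own value, as log2 signal without the floor. Scores are the mean floored log2 signal of a list's members in a cell.

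The 20 gene lists were fixed before the data were examined and hold 224 symbols, of which 209 were measured: germ cell specification, pluripotency network, primed epiblast, primitive streak and mesoderm (called mesoderm regulators in the text), Hox genes, allantois and extraembryonic mesoderm, mesenchymal, epithelial, DNA methylation and demethylation, histone methylation, proliferation, cell cycle inhibitors, BMP response, visceral and definitive endoderm, trophoblast, blood and endothelium, neural plate, immediate early and stress, housekeeping, and Y linked and Xist. T, Nanos3 and Gapdh are among the genes not analysed here for lack of a probe set with 1 symbol. Dnmt3b, Cdx2, Msx1 and Msx2 stand in more than 1 list. The median over members was set against 10000 random lists of the same size, as a description of these cells. The random lists were matched on mean signal over all cells in 50 bins. Members differing by at least 1 log2 unit were counted as a statement of size. Shifts of whole arrays are given as the median over the 7221 genes detected in at least 50% of all cells, called broadly detected genes. Genes named in the text were chosen by a rule also fixed beforehand: in each comparison the 10 largest positive and the 10 largest negative differences among genes detected in at least 75% of the cells of the higher group, the list members, the genes used to choose cells, and Ifitm3; Abca4, Ppp2cb, Naa20, Senp3 and the other genes that follow sets of arrays were followed across all groups after their values were seen.

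The comparisons were E8.25 PGCs with pre-streak epiblast and the steps between them, E/MB PGCs with posterior mesoderm, PGCs with Blimp1+ Hoxb1+ cells, knockout with wild-type cells at LS/0B and at E/MB, and E/MB knockout cells with posterior mesoderm. Correlations across genes used 8910 genes detected in at least 25% of all cells. Alternatives planned beforehand were quantile normalization, scaling to the spiked lys control (3 probe sets), no floor, a floor 2 times higher, the log2 of mean linear signal, medians over cells, the mean of all probe sets of a gene, the 99th percentile as detection limit, pooling the 4 cells with disagreeing stage labels, LS/0B precursors as the reference for E/MB knockout cells, leaving out cells over 3 scaled MADs below the median number of detected probe sets, and leaving out each cell in turn. In simulated data for the LS/0B knockout comparison over 18193 genes, differences of 1 and 2 log2 units were put into 100 genes each. These genes had signal well above the floor, and noise was drawn independently for each probe set. The differences were recovered as 0.986 and 1.973 on average, with the right sign in 99% and 100% of genes. Of 40 unchanged lists drawn from equally bright genes, 1 lay outside the 2.5th to 97.5th percentile of random lists. The simulation does not cover genes near the floor, genes detected in only part of the cells, or lists whose members vary together. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.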

Results

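The series profiled single mouse cells along the path from the posterior epiblast to primordial germ cells (PGCs), the embryonic founders of sperm and eggs, together with neighbouring mesoderm and cells lacking Blimp1. Blimp1, the product of Prdm1, is a transcriptional repressor needed for PGC formation. Each array measured the amplified cDNA of 1 cell from a C57BL/6 embryo, and the cells fell into 11 groups by stage, genotype and the transcripts used to choose them. The wild-type lineage comprised 8 posterior epiblast cells at the pre-streak (PS) stage, 7 PGC precursors at the Early/Mid-Streak (E/MS) stage, 17 precursors at the Late-Streak/0-Bud (LS/0B) stage, and PGCs at the Early/Mid-Bud (E/MB), early head fold (EHF) and E8.25 stages with 8 cells each. Beside these stood 10 posterior mesoderm cells at E/MB, 4 Blimp1+ Hoxb1+ cells at E/MB, 4 Blimp1+ Hoxb1+ cells labelled EHF in their description but E/MB in their title, and Blimp1 knockout cells at LS/0B (20) and E/MB (12). The labels name no embryo or litter, so each group counted as 1 sample. Differences are therefore given in log2 units of array signal with the SD over cells, as values of these cells without a test.

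Group means of detected probe sets per cell lay between 9927.7 (mesoderm) and 11422.9 (LS/0B knockout). At the stricter limit, the 99th percentile of background probe sets, groups that are compared below differed more: 8534 ± 645 in E8.25 and 8046 ± 414 in E/MB PGCs, against 6740 ± 869 in E/MB knockout cells, 6454 ± 242 in Blimp1+ Hoxb1+ EHF cells and 6336 ± 864 in mesoderm. Hybridisation controls, which are added after amplification, averaged 10.16 ± 0.47 log2 units (SD, n = 10) on the mesoderm arrays and 8.34 ± 0.33 (n = 96) on all others, and the lowest mesoderm array (9.54) lay above the highest of the others (9.47). Xist, the transcript of the inactive X chromosome, and Y-linked transcripts never occurred in the same cell: 23 cells had Xist, 74 had a Y-linked transcript and 0 had both. The remaining cells had neither, so their sex is not known. Among them were 2 of 8 E8.25 PGCs and 2 of 12 E/MB knockout cells. All 8 epiblast cells had Xist, whereas it was detected in 0 of 8 E8.25 PGCs and 0 of 32 knockout cells; LS/0B precursors were mixed, with 8 Xist and 8 Y-linked cells among 17.

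**Figure D1:**
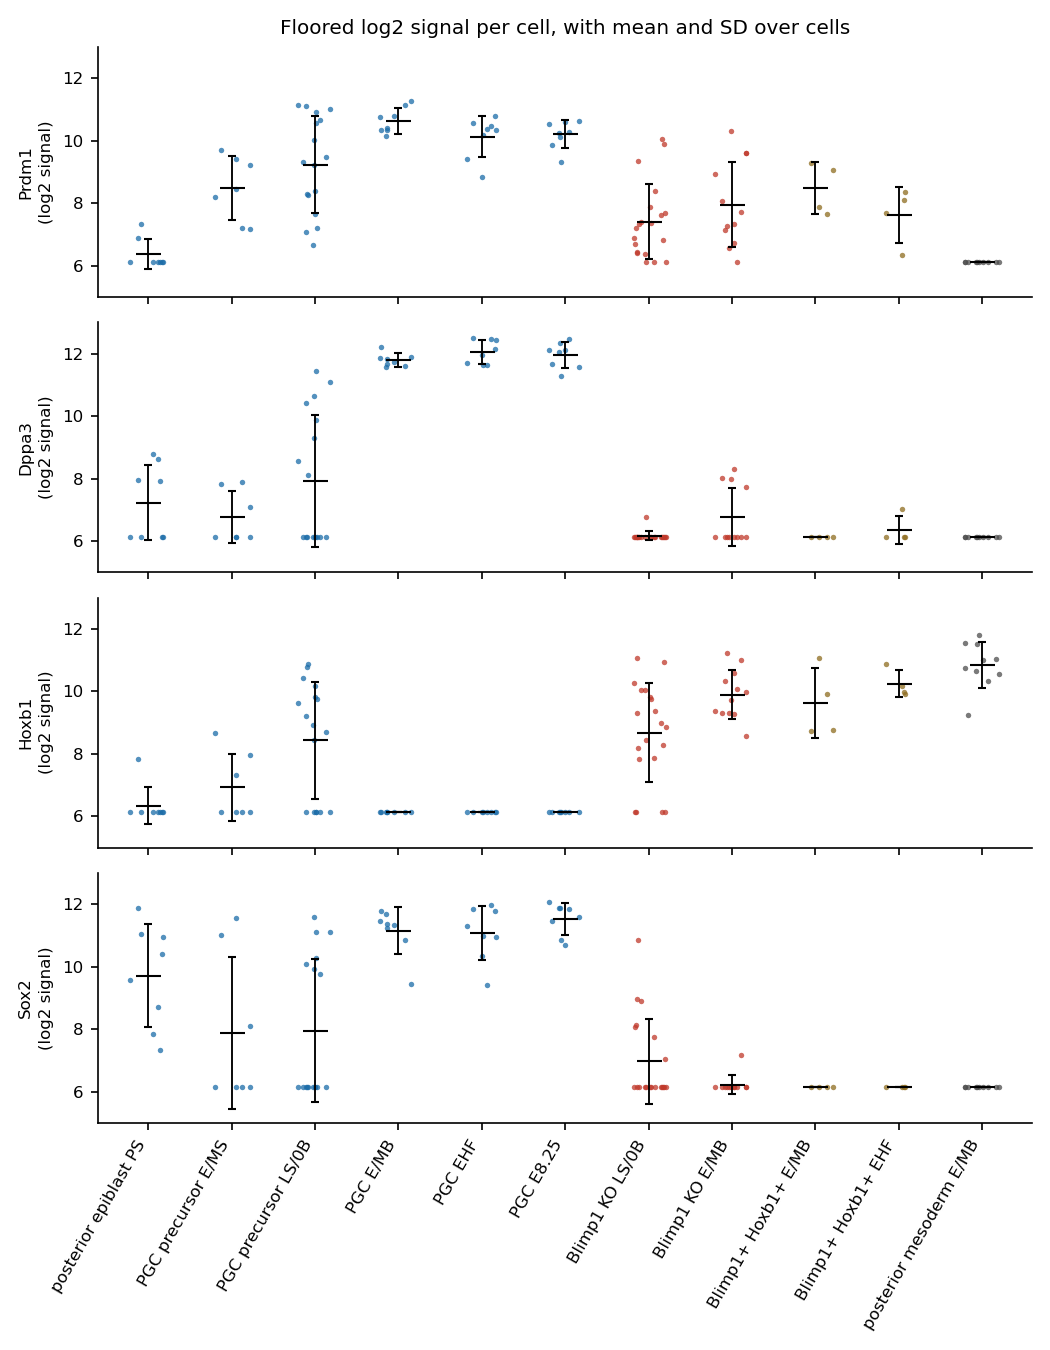
Floored log2 signal of Prdm1, Dppa3, Hoxb1 and Sox2 in each cell, by group; each point is 1 cell, and bars give the mean ± SD over cells. All 24 PGCs had Dppa3 and Sox2 and 0 had Hoxb1, while LS/0B precursors held cells at the floor and cells well above it for Dppa3, Hoxb1 and Sox2.

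Of the 20 gene lists, germ cell specification had the largest median difference between E8.25 PGCs and pre-streak epiblast. Of 11 measured genes of this list, 9 were higher by at least 1 log2 unit and 0 were lower, with a median difference of 3.11, above all 10000 random lists matched on mean signal. Kit, the receptor for stem cell factor, averaged 11.18 ± 0.33 (SD, n = 8) in PGCs and 6.44 ± 0.58 (n = 8) in epiblast, a difference of 4.74. Dnd1, an RNA-binding protein needed for PGC survival, was higher by 3.84, the surface protein gene Ifitm1 by 3.11 and the alkaline phosphatase gene Alpl by 3.82. Prdm14 and Tfap2c, transcription factors of the germ lineage, were detected in 6 and 7 of 8 PGCs and in 0 of 8 epiblast cells. Prdm1 (3.83) and Dppa3 (4.73) were also higher, but PGCs had been chosen for them; without these and Ifitm3 the list median was 2.73, with 6 of 8 genes higher.

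Genes of the primed epiblast went the other way, with 6 of 11 lower by at least 1 log2 unit, 1 higher, and a median of -2.04. Dnmt3b, a de novo DNA methyltransferase, averaged 12.66 ± 0.14 in epiblast and 6.91 ± 1.51 in E8.25 PGCs (-5.76; n = 8 each), and Pim2 (-5.28), Nodal (-3.03) and Otx2 (-2.76) were lower as well. Sox3 was the exception, at 2.27. Genes of DNA methylation had a mean difference of -1.48, carried by 3 of 8 members: Dnmt3b, Dnmt3a (-2.80) and Uhrf1 (-2.85), the partner of the maintenance methyltransferase. BMP response genes were higher in 5 of 9 cases with a median of 1.29, among them Msx1 (3.48), Msx2 (2.36) and Id1 (2.21). The pluripotency network split, with 5 of 17 members higher and 3 lower: Klf2 (3.89), Klf5 (2.70) and Sox2 (1.81) were higher, whereas Tdgf1 (-5.39), Dppa5a (-2.63) and Nanog (-1.11) were lower. Its mean difference was 0.13, within the SD over cells of its score, and its median was -0.02, or 0.18 when 1 epiblast cell, replicate 7, was left out.

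Outside the lists, Mbp, the gene of myelin basic protein, was at least 12.2-fold higher in E8.25 PGCs, where all 8 cells had it, and the iron exporter gene Slc40a1 was higher by 4.27, Mfge8 by 4.13, the histone variant gene Macroh2a1 by 4.11 and glycogen phosphorylase Pygl by 3.95. In epiblast, the neurofilament gene Nefl was at least 24.2-fold higher, the gap junction gene Gja1 at least 12.6-fold and Prps1, an enzyme of nucleotide synthesis, at least 11.5-fold. Car4 (-5.27), Tcfl5 (-4.81) and the apoptosis gene Pmaip1 (-4.37) were lower in PGCs. Xist was at least 18.1-fold higher in epiblast, in parallel with the difference in cell sex described above.

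The first step, from epiblast to E/MS precursors, combined higher mesenchymal with lower epithelial transcripts. Of 10 mesenchymal genes 6 were higher by at least 1 log2 unit and 0 lower (median 1.84), including the cadherin genes Cdh11 (3.51) and Cdh2 (2.74), fibronectin Fn1 (2.78), the growth factor receptor Pdgfra (2.81) and Snai1 (2.35), a repressor of E-cadherin. Of 9 epithelial genes 6 were lower and 1 higher (median -1.18, or -0.76 without E/MS replicate 1), among them E-cadherin Cdh1 (-2.67) and Cldn6 (-2.79), with the desmosomal gene Dsp (2.96) opposite. Mesoderm regulators were higher in 5 of 14 cases with 0 lower: Mesp1 averaged 11.53 ± 1.95 (n = 7) in precursors and 6.56 ± 0.45 (n = 8) in epiblast, and Mixl1 (3.50) and Lhx1 (2.88) were higher too. Allantois genes (median 0.71, or 0.36 without E/MS replicate 7; 5 of 12 higher) and BMP response genes (median 0.82, 3 of 9 higher) went with them, while primed epiblast genes were lower in 5 of 11 cases (median -0.95). Germ cell genes had moved little at this step, with 2 of 11 higher, Prdm1 (2.11, used as a gate) and Ifitm1 (1.65), and a mean difference of 0.32, or 0.16 without E/MS replicate 5. Other large differences were in Tbx3 (3.40), Greb1 (3.31), Rbms1 (3.06) and Ppic (2.83), against Utf1 (-3.58), the sterol enzyme Sqle (-3.17), Spint1 (-2.92), Mid1ip1 (-2.82) and Camsap3 (-2.70). Sex differed at this step too, with Xist in 8 of 8 epiblast cells and 0 of 7 precursors.

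At LS/0B, 5 of 11 germ cell genes were higher than at E/MS by at least 1 log2 unit and 0 were lower, with a median of 0.82 and a mean of 1.04. With the 8 LS/0B cells that have Xist left out, these were 0.30 and 0.58. Prdm14 was higher by 2.80 and was detected in 11 of 17 cells against 0 of 7, Dnd1 was higher by 1.83 (1.21 without the Xist cells) and Tfap2c by 1.26 (0.64). The cells differed widely among themselves: Dppa3 averaged 7.92 ± 2.11 (n = 17), and 5 cells had Dppa3 without Hoxb1, 8 had Hoxb1 without Dppa3, 3 had both and 1 neither. This split went with sex and with a block of replicates, which cannot be separated: all 5 cells with Dppa3 alone had Xist, as did 6 of the 7 with Sox2, and Hoxb1 was in 2 of 8 cells with Xist and 9 of 9 without. The germ cell score was 8.02 ± 0.81 (n = 9) without Xist and higher by 0.98 with it (n = 8, SD 1.06). The Xist cells were replicates 14 and 18 to 24, the others 1 to 8 and 16, and Ppp2cb, which follows sets of arrays, was detected in 6 of 8 and 0 of 9 of them. Cell cycle inhibitors had a mean difference of 0.62, from Cdkn1c (2.75) and Cdkn1a (1.49), and Cdx2 (2.22, or 1.42 without the Xist cells), Bmp4 (1.98), Kitl (at least 3.21-fold) and Fos (2.68) were higher. Dppa5a (-3.00), Pim2 (-2.05), Tdgf1 (-2.41, or -1.23 without the Xist cells) and Dnmt3b (-1.60, or -0.53) were lower, and so were the mesenchymal genes Cdh11 (-1.92), Snai1 (-1.64) and Pdgfra (-1.43). Among epithelial genes Cdh1 (1.57) and Krt8 (1.44) were higher, but the list median of 0.46 was 0.023 without the Xist cells and 0.042 without E/MS replicate 1. Xist was detected in 8 of 17 cells at LS/0B and 0 of 7 at E/MS.

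Between LS/0B precursors and E/MB PGCs the germ cell list took the largest of its steps, with 8 of 11 genes higher by at least 1 log2 unit, 0 lower and a median of 1.66. Kit averaged 10.25 ± 1.17 (n = 8) in PGCs and 6.73 ± 1.06 (n = 17) in precursors, Dnd1 was higher by 1.98, Prdm14 by 1.91 and Tfap2c by 1.66. Sox2, a core pluripotency factor, was higher by 3.20 and was detected in 8 of 8 PGCs against 7 of 17 precursors. Mesoderm regulators were lower in 4 of 14 cases with 1 higher (median -0.44), including Mixl1 (-2.87), Mesp1 (-2.46) and Eomes (-1.80). Mesenchymal genes were lower in 4 of 10 cases and higher in 0, Hoxb1 and Hoxb2 were detected in 0 of 8 PGCs, and Uhrf1 (-3.08) was detected in 2 of 8 PGCs and 17 of 17 precursors. Immediate early genes, which respond within minutes to stimuli such as tissue handling, were lower in 5 of 10 cases (median -0.87), among them Egr1 (-2.99) and Fos (-2.57). The PGCs of this step had been chosen for Dppa3 and the precursors for Pou5f1, so Dppa3 (3.88) is not a finding. The count and median of the germ cell list include Dppa3, Prdm1 and Ifitm3, and were not computed without them here. Precursors were not chosen for Dppa3, and their germ cell scores ran from 7.26 to 9.95. Part of the size of this step can therefore come from the change in how cells were chosen. Of the precursors 8 of 17 had Xist, and of the PGCs 0 of 8.

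From E/MB to EHF and E8.25 the germ cell score stayed at 10.18 ± 0.18, 10.15 ± 0.16 and 10.01 ± 0.24 (n = 8 each). Pluripotency genes had a mean difference of 0.31 at each step, but 1 EHF cell, replicate 6, carried much of the first, which was 0.18 without it; Utf1 was higher by 1.69 (1.03 with EHF cells without Xist only) and then by 1.37, and Dppa5a by 1.58 at the last step. At EHF, Etv4, a target of FGF signalling, was at least 6.25-fold higher and the NF-kappaB inhibitor gene Nfkbia at least 3.21-fold higher than at E/MB, and Cdx1 was higher by 2.25, while Dock11 (-2.44), Pink1 (-2.34) and Mmp2 (-2.33) were lower. At E8.25, Igfbp2 (2.18, or 1.41 against EHF cells without Xist), Cox10 (2.13) and the replication licensing gene Cdc6 (1.90) were higher than at EHF. Prdm14 averaged 8.35 ± 1.36 at E8.25 and 10.51 ± 0.45 at EHF (-2.16), and cell cycle inhibitors had a median of -0.60 (-0.31 against EHF cells without Xist), with Cdkn1a at -1.34. Sex differed at both steps, with Xist in 0 of 8 E/MB, 5 of 8 EHF and 0 of 8 E8.25 PGCs. Of the E8.25 PGCs, 2 of 8 had no Y-linked transcript either, so their sex is not known.

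**Figure D2:**
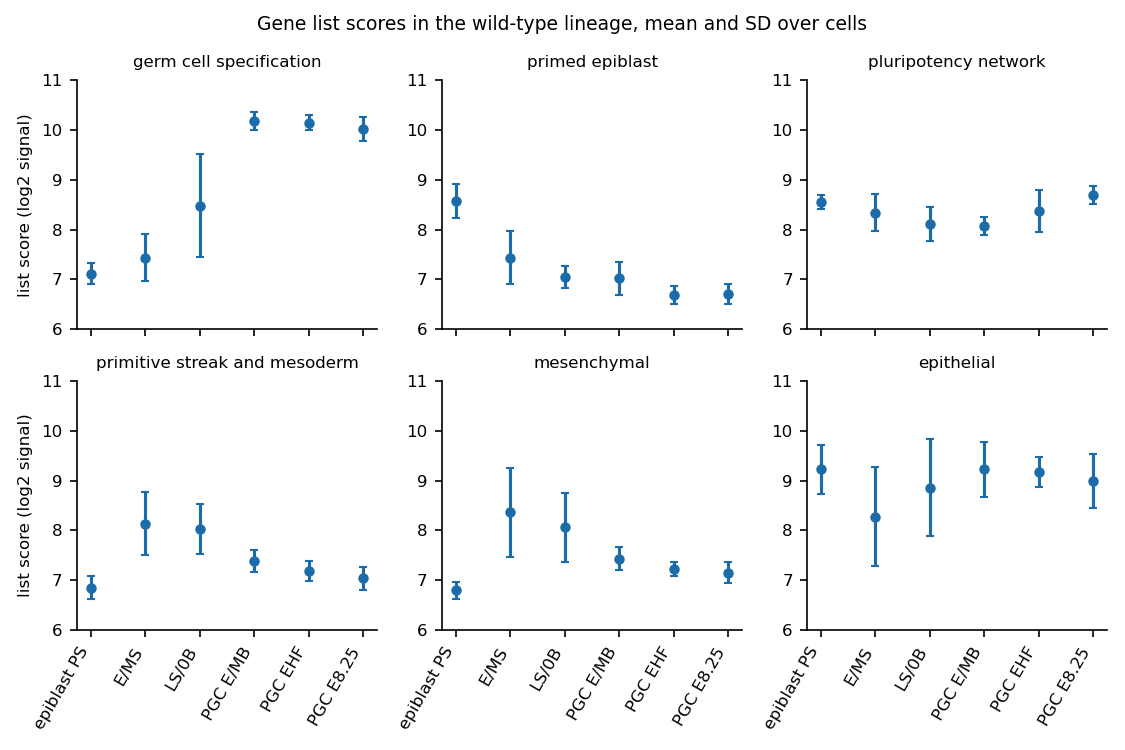
Mean ± SD over cells of 6 gene list scores (mean floored log2 signal of the members) along the wild-type lineage, from pre-streak epiblast to E8.25 PGCs. The germ cell score went from 7.12 in epiblast to 10.18 at E/MB with its widest spread at LS/0B (SD 1.04), and the mean mesenchymal score was highest at E/MS (8.36, SD 0.89).

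The comparison of E/MB PGCs with posterior mesoderm from the base of the allantois asks how germ cells differ from their somatic neighbours of the same stage. Germ cell genes were higher in PGCs by at least 1 log2 unit in 9 of 11 cases, with 0 lower and a median of 2.97. Prdm14 averaged 10.84 ± 0.47 (n = 8) in PGCs and 6.40 ± 0.85 (n = 10) in mesoderm, Kit was higher by 3.97, Dnd1 by 3.68 and Tfap2c by 2.94. Sox2 was at least 18.3-fold higher, with 8 of 8 PGCs and 0 of 10 mesoderm cells above detection (an exact 95% interval of 0% to 30.8% for the latter), and Nanog (3.13) and Klf2 (2.37) were higher as well. Prdm1, Dppa3 and Hoxb1 had been used to choose the cells; without Prdm1, Dppa3 and Ifitm3 the germ cell median was 2.24. Sox3 (4.45), Socs2 (4.31), Serinc5 (4.11), Pdcd4 (4.05) and Pdpn (3.99) were higher, and AU015836 was at least 17.7-fold higher.

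Part of the mesenchymal, Hox and allantois genes were higher in mesoderm. Mesenchymal genes were lower in PGCs in 3 of 10 cases with 0 higher (median -0.51): Snai1 was at least 6.62-fold lower and Pdgfra (-2.91) was detected in 0 of 8 PGCs and 10 of 10 mesoderm cells. Of 14 mesoderm regulators 5 were lower and 2 higher (median -0.24), with Mesp1 at -3.81, Mixl1 at -2.99, Cdx1 at -2.46 and Msgn1 at -2.44. Hox genes had 3 of 16 members lower, Hoxb2 (-2.49), Hoxd9 (-2.80) and Hoxb1, by which mesoderm cells were chosen and without which the list median was -0.18, and the allantois list 4 of 12 lower against 1 higher, with Isl1 (-2.43) and Foxf1 (-2.39) lower and Msx1 (1.65) higher. The growth factor gene Fgf3 was at least 8.88-fold lower in PGCs, the apelin receptor Aplnr at least 6.51-fold and Gja1 at least 5.31-fold, and Dnmt3b (-3.11), Gins2 (-3.06) and prostacyclin synthase Ptgis (-3.47) were lower. Epithelial genes were higher in PGCs, with a mean difference of 1.18 and 4 of 9 members higher, among them Cldn7 (3.44), Esrp1 (3.26) and Cdh1 (2.46). The mesoderm arrays were those with the higher hybridisation controls (10.16 against 8.34), so array set and cell type coincide here. Scaling to the spiked lys control shifted the median of the broadly detected genes from 0.15 to -0.40. With it the Hox median moved to -0.73, the mesenchymal median to -1.10 and the germ cell median to 2.40. Without the floor the mesoderm regulators had a median of -0.96.

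A second reference came from Blimp1+ Hoxb1+ cells, which had Blimp1 and Oct4 but also Hoxb1. The labels name them by these transcripts only, so whether they are somatic is not settled. At E/MB their germ cell score was 8.13 ± 0.07 (n = 4). It was 7.37 ± 0.32 (n = 10) in mesoderm and 8.02 ± 0.81 (n = 9) in LS/0B precursors without Xist. The arrays of the Blimp1+ Hoxb1+ cells at both stages stand apart from all PGC arrays in Abca4 and Ppp2cb, so array set and cell type coincide here as well. At E/MB, 8 of 11 germ cell genes were higher in PGCs by at least 1 log2 unit, with 0 lower and a median of 1.99 (1.52 without the gated genes). Dnd1 averaged 10.92 ± 0.63 (n = 8) in PGCs and 6.96 ± 1.66 (n = 4) in Blimp1+ Hoxb1+ cells, Prdm14 was higher by 3.10, Kit by 2.29 and Tfap2c by 1.99. Sox2 was at least 20.3-fold higher, with 0 of 4 Blimp1+ Hoxb1+ cells above detection, which allows a share of up to 60.2% by the exact interval. The pluripotency list had 5 of 17 members higher and 2 lower, with a mean of 0.54. Prdm1 itself was higher by 2.17 in PGCs although both groups were chosen for it.

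Mesenchymal genes were lower in E/MB PGCs than in Blimp1+ Hoxb1+ cells in 4 of 10 cases with 0 higher (median -0.85), including Pdgfra (-3.08) and Cdh2 (-3.04). Allantois genes were lower in 4 of 12 cases (median -0.39), with Isl1 at -3.98 and Foxf1 at -2.82, and BMP response genes in 3 of 9 (median -0.64), with Smad6 at -3.09 and Id2 at -2.01. Immediate early genes were lower in 5 of 10 cases, with a median of -1.13. Myc was at least 8.88-fold lower in PGCs and Gja1 at least 13.3-fold, and Apela (-4.02), Car4 (-3.77), Col9a1 (-3.69), Uhrf1 (-3.56) and the imprinted gene Mest (-3.39) were lower. Socs2 (3.85), Plcg2 (3.68), Sox3 (3.49) and Slc40a1 (3.35) were higher, and Tsga8 and Hmbox1 were at least 6.78-fold and 6.87-fold higher. With 1 Blimp1+ Hoxb1+ cell, replicate 3, left out, the pluripotency median was 0.21. Scaling to the lys control shifted the median of the broadly detected genes from 0.05 to 0.21.

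The EHF pair, whose 4 Blimp1+ Hoxb1+ cells carry disagreeing stage labels, showed wider differences in some of these lists, but not in immediate early genes, which had a mean of 0.23 with 1 of 10 higher and 1 lower. Germ cell genes were higher in PGCs in 7 of 11 cases with 0 lower (median 2.49, or 1.75 without the gated genes), with Prdm14 at least 11.9-fold and Kit at least 14.7-fold higher. Pluripotency genes were higher in 8 of 17 cases and lower in 1, with Nanog at 3.70 and Utf1 at 2.38. Epithelial genes were higher in 5 of 9 (median 1.80), with Cdh1 at 4.13 and Esrp1 at 4.03. Hox genes were lower in PGCs in 6 of 16 cases (median -0.70, or -0.67 without Hoxb1), with Hoxd9 at -4.15 and Hoxb6 at -2.92, mesenchymal genes in 5 of 10 (median -1.28) and allantois genes in 6 of 12 (median -0.78), where Foxf1 was at least 19.2-fold and Isl1 at least 10.9-fold lower. L1td1 was at least 14.2-fold higher in PGCs, and Fabp7 (-4.48), Tpm1 (-4.32) and Cited1 (-4.20) were lower. Whether these wider differences reflect stage was not tested, and Xist was in 5 of 8 PGCs and 1 of 4 Blimp1+ Hoxb1+ cells.

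Blimp1 knockout cells were compared with wild-type precursors at LS/0B to ask which genes depend on Blimp1 when the germ lineage first forms. The Prdm1 probe set gave signal in 12 of 20 knockout cells (7.41 ± 1.20) against 16 of 17 wild-type cells (9.24 ± 1.54). Whether it can detect the mutant transcript used to choose these cells was not established, since the position of the deletion is not given in the sources used here. Germ cell genes were lower in knockout cells by at least 1 log2 unit in 6 of 11 cases, with 0 higher and a median of -1.14. Dppa3 was detected in 0 of 20 knockout cells (exact 95% interval 0% to 16.8%) and 8 of 17 wild-type cells, Tfap2c (-1.24) in 1 of 20 and 9 of 17, and Dnd1 (-2.20) in 7 of 20 and 12 of 17. The germ cell score was 7.55 ± 0.48 (n = 20) in knockout and 8.48 ± 1.04 (n = 17) in wild-type cells, and 1 of 20 knockout cells lay above the wild-type mean. Many wild-type cells lay below that mean too. Wild-type scores ran from 7.26 to 9.95 and knockout scores from 6.83 to 8.79, so the groups overlapped. Without Prdm1 and Ifitm3, used for choosing and screening cells, and Dppa3, which was not used to choose cells at this stage, the list had a median of -0.39 and a mean of -0.69 in place of -0.93, with 3 of 8 genes lower.

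The sexes of the cells differed in this comparison, with Xist in 8 of 17 wild-type and 0 of 20 knockout cells. Against the 9 wild-type cells without Xist the germ cell median was -0.55 in place of -1.14, 2 of 11 genes were lower, and Prdm1 was at -1.01, Dppa3 at -0.81, Prdm14 at -0.74 (-1.48 over all cells) and Tfap2c at -0.62; Dnd1 was at -1.59. Hoxb1 was at 0.24 against all wild-type cells and at -0.93 against those without Xist, both within the SD over cells.

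Mesenchymal genes were higher in LS/0B knockout cells in 3 of 10 cases with 0 lower (median 0.32, 0.46 against cells without Xist): Pdgfra averaged 9.93 ± 1.51 and 7.77 ± 1.96, Cdh11 was higher by 1.39 and Snai1 by 1.06. Against cells without Xist 2 of 10 were higher, Pdgfra (1.72) and Vim (1.18), with Cdh11 at 0.94 and Snai1 at 0.75. BMP response genes had a median of 0.45 (0.76 without Xist cells), led by Smad6 (1.21), and Dnmt3b was higher by 1.51, but by 0.44 against cells without Xist. Car4 (2.38, or 1.59 without Xist cells), Gja1 (2.03), Mest (2.03) and Myc (1.72) were higher, while immediate early genes had a median of -0.50 and Fos (-2.62), the laminin gene Lama3 (-1.67), Hook1 (-1.42) and Porcn (-1.35), needed for Wnt secretion, were lower. Mesoderm regulators and Hox genes differed little, with mean differences of -0.0019 and 0.052, and 11 of 20 knockout cells lay above the wild-type mean for each. Abca4 (-2.28), Ppp2cb (1.78), Naa20 (2.19), Senp3 (2.30) and Igfbp4 (1.79) were among the largest differences as well. These genes differed from the lineage groups in the same direction in the Blimp1+ Hoxb1+ groups, a set of arrays wider than the genotype. Abca4 was detected in 56 of 56 cells of the 6 lineage groups, 1 of 40 cells of the 4 knockout and Blimp1+ Hoxb1+ groups and 6 of 10 mesoderm cells, and Ppp2cb in 9 of 56, 38 of 40 and 8 of 10. Igfbp4 separated these sets less sharply, in 34 of 56, 37 of 40 and 10 of 10 cells. For it, array set and kind of cell cannot be told apart.

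**Figure D3:**
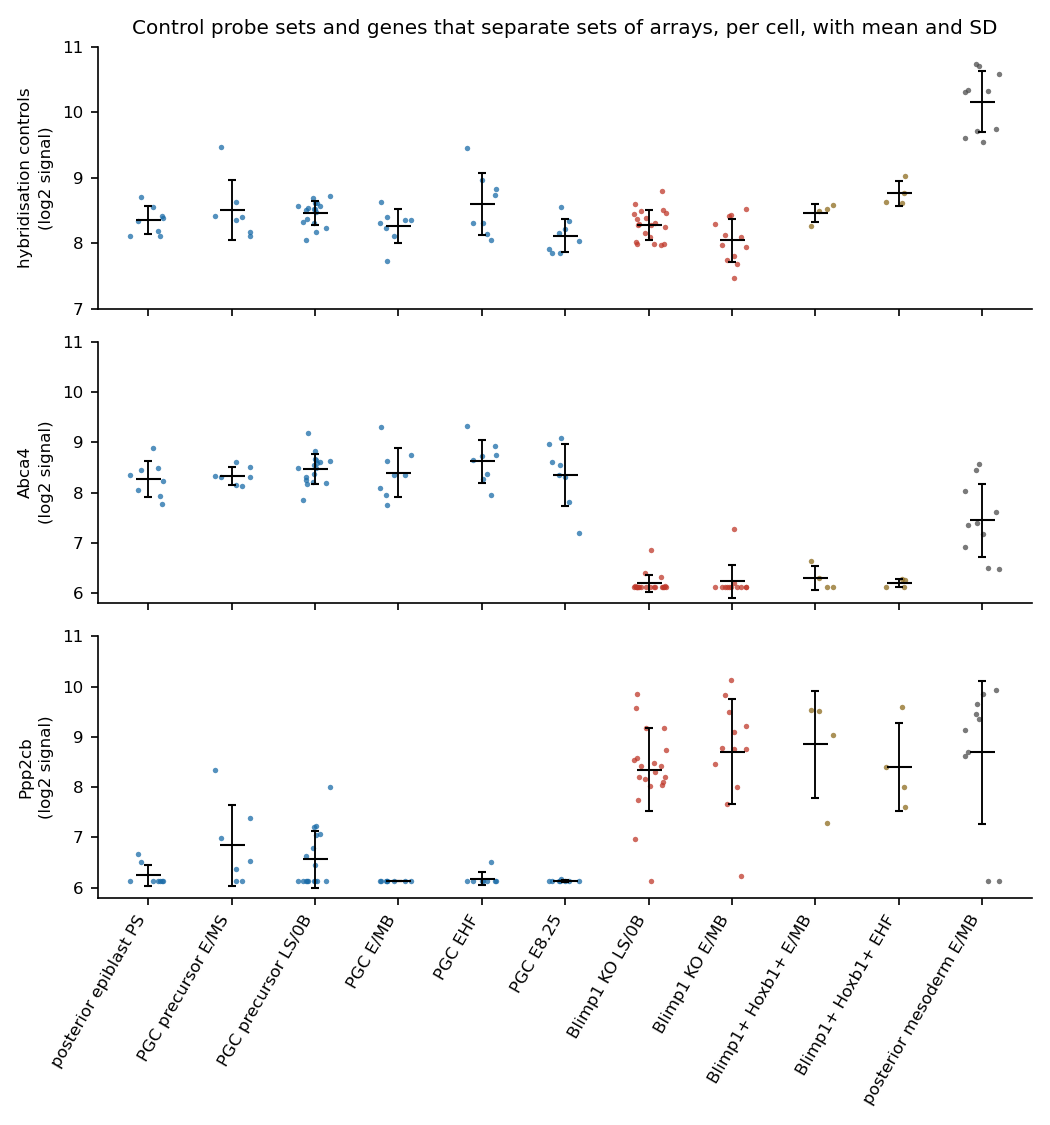
Log2 signal of the hybridisation control probe sets, Abca4 and Ppp2cb in each cell, by group, with mean ± SD over cells. The controls are higher on the mesoderm arrays (10.16 against 8.34), and Abca4 is near the floor in all 4 knockout and Blimp1+ Hoxb1+ groups (6.22 against 8.42 in the lineage groups).

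At E/MB, knockout cells were compared with wild-type PGCs. Prdm1 averaged 7.96 ± 1.36 (n = 12) in knockout cells and 10.64 ± 0.42 (n = 8) in PGCs. Germ cell genes were lower by at least 1 log2 unit in 8 of 11 cases with 0 higher and a median of -2.69, or -2.07 with 5 of 8 genes lower without the gated ones. Dnd1 (-3.88), Prdm14 (-3.41), Tfap2c (-2.83, in 0 of 12 knockout cells, exact 95% upper limit 26.5%), Kit (-2.18) and Alpl (-1.95) were lower. The mean PGC score was reached by 0 of 12 knockout cells, but this score includes Prdm1, Dppa3 and Ifitm3. Sox2 averaged 6.22 ± 0.30 in knockout cells, with 1 of 12 above detection, and Nanog (-2.03) and Klf2 (-2.18) were lower; the pluripotency list had 5 of 17 members lower and 1 higher, Tbx3 (2.13). PGCs had been chosen for Dppa3 and knockout cells for Pou5f1, so Dppa3 (-5.04, in 4 of 12 knockout cells) is not a finding. Leaving out the gated genes does not undo this choice, since choosing cells for Dppa3 can also select for other germ cell transcripts. Blimp1+ Hoxb1+ E/MB cells, chosen for Hoxb1 and not for Dppa3, had a germ cell score of 8.13 ± 0.07 (n = 4). The score was 7.84 ± 0.74 (n = 12) in knockout cells and 10.18 ± 0.18 (n = 8) in PGCs. The difference between LS/0B and E/MB was not tested, and the reference cells of the stages were chosen by different genes.

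Some Hox, mesenchymal and allantois genes were higher in the E/MB knockout cells. The knockout arrays also differ from the PGC arrays in Abca4 and Ppp2cb, so array set and genotype coincide. Hox genes were higher in 5 of 16 cases with 0 lower (mean 0.81), with Hoxb1 at least 8.26-fold higher and Hoxb2 (3.22) detected in 12 of 12 knockout cells and 0 of 8 PGCs. Mesenchymal genes were higher in 5 of 10 cases with 0 lower (median 0.93), including Cdh11 (2.83), Pdgfra (2.12) and Snai1 (1.93), and allantois genes in 5 of 12 (median 0.70), including Isl1 (2.23) and Foxf1 (2.17). Genes of DNA methylation were higher in 3 of 8 cases with a mean of 1.13: Dnmt3b averaged 11.44 ± 0.31 and 7.89 ± 1.63, Uhrf1 was higher by 3.28 and Dnmt3a by 2.08. Smad6 (2.52) and Id2 (1.98) led the BMP response genes, and Mesp1 (2.46) the mesoderm regulators, 3 of 14 of which were higher and 1 lower. Gja1 was at least 16.1-fold higher, Aplnr at least 6.24-fold and Myc at least 4.96-fold, and Car4 (4.26), Apela (3.95), Ptgis (3.53) and Prps1 (3.31) were higher, as was Spin2c (3.52), which like Igfbp4 is higher in all knockout and Blimp1+ Hoxb1+ groups than along the lineage; AU015836 (-4.03), Slc40a1 (-3.59), Socs2 (-3.58), Plcg2 (-3.26) and Uap1l1 (-3.20) were lower. Against LS/0B precursors in place of E/MB PGCs the germ cell median was -1.16 and the mesenchymal median 0.47. With this reference, of an earlier stage and not chosen for Dppa3, 22 of 23 values of named genes moved by more than the SD over cells. Of the list medians 5 of 20 did, and 0 values were counted as changed in sign. The sizes of the gene differences given here therefore depend on the reference. Scaling to the lys control shifted the median of the broadly detected genes from 0.01 to 0.62, and the pluripotency median from -0.26 to 0.0027. That median was also 0 from medians over cells and from the mean of all probe sets, so it has no settled direction. The mean over the list was -0.61, with scores of 7.46 ± 0.23 (n = 12) and 8.06 ± 0.18 (n = 8) and 0 of 12 knockout cells above the PGC mean. Without the floor the mesenchymal median was 2.38 and the Hox median 0.48.

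**Figure D4:**
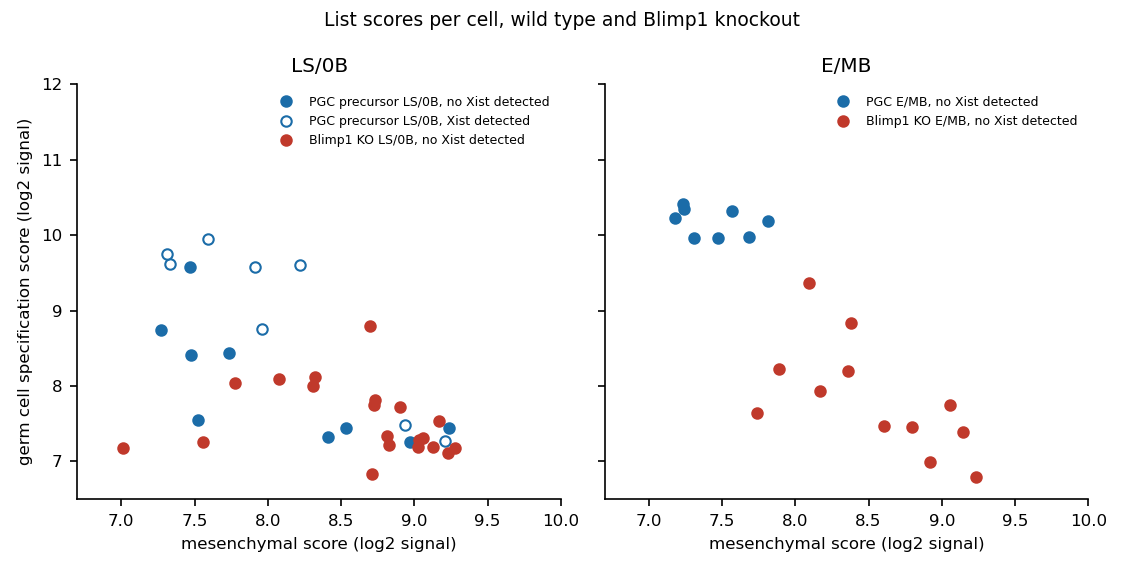
Germ cell specification score against mesenchymal score (log2 signal) of each wild-type and Blimp1 knockout cell at LS/0B and at E/MB; open symbols mark cells with Xist. At E/MB the 12 knockout cells lie apart from the 8 PGCs, and at LS/0B 17 of 20 knockout cells lie above the wild-type mean mesenchymal score.

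The last comparison set E/MB knockout cells beside posterior mesoderm, to ask how far they resembled somatic neighbours. The germ cell list differed by a median of 0.16, with 3 of 11 genes higher in knockout cells and 0 lower: Kit (1.78), Prdm14 (1.04) and Prdm1, for whose absence mesoderm cells were chosen. Without Prdm1, Dppa3 and Ifitm3 the median was 0.052 and the mean 0.32, with 2 of 8 genes higher. The germ cell score was 7.84 ± 0.74 (n = 12) in knockout cells and 7.37 ± 0.32 (n = 10) in mesoderm. Knockout replicates 6 to 9 scored from 8.20 to 9.37, above the highest mesoderm cell (8.10). This score includes Prdm1, for whose absence mesoderm cells were chosen. Dppa3, also in the score, was detected in 4 of 12 knockout and 0 of 10 mesoderm cells. Hox genes differed by a mean of -0.02 and mesenchymal genes by a median of 0.06, both within the SD over cells of the scores. Epithelial genes were higher in knockout cells in 5 of 9 cases (median 1.03), with Krt18 at 2.39 and Krt8 at 1.62. The anchoring protein gene Akap12 (3.27), Rbm25 (3.22), Nusap1 (2.99), Cd24a (2.91), Nkx1-2 (2.79), Birc6 (2.76), Arhgap29 (2.73) and Myh9 (2.57) were higher, and Gal (at least 2.01-fold), Cdc42ep1 (-1.93), Psmd7 (-1.93) and Lsg1 (-1.79) were lower. Mesoderm regulators were lower in 4 of 14 cases and higher in 1 (median -0.23), with Msgn1 at -1.90, and BMP response genes had a median of 0.79. Here too the mesoderm arrays had the higher hybridisation controls, and array set and cell type cannot be told apart. With the 4 Blimp1+ Hoxb1+ E/MB cells in place of mesoderm, almost no difference was left in some values. The mesoderm regulators had a median of 0.016, the BMP response genes -0.011, and Firre was at -0.0097 in place of 2.78. Msgn1 (0.24), Dll1 (0.73 in place of -1.89), Car3 (0.19 in place of -1.77) and Tafa5 (0.58 in place of -1.69) had smaller differences in the opposite direction.

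Spread between cells differed among groups for the germ cell score. Its SD was 0.18 in E/MB PGCs, 1.04 in LS/0B precursors, 0.48 in LS/0B knockout cells and 0.74 in E/MB knockout cells. Of these groups only the E/MB PGCs were chosen for Dppa3, a member of the list. Their narrow spread can therefore come in part from the choice of cells, and no SD without the gated genes was computed. Across 8910 genes, which are not independent replicates, the LS/0B knockout difference correlated with the difference between E/MB PGCs and mesoderm with Pearson's r of -0.219 and Spearman's rho of -0.146; these comparisons share no cell. With the EHF pair of PGCs and Blimp1+ Hoxb1+ cells, r was -0.356 and rho -0.314, and the PGC comparisons correlated with each other with r of 0.399 and rho of 0.296. Each of these comparisons also sets lineage arrays against other arrays, so a shared array effect is not excluded as the source of these signs. No value without a difference was computed.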

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

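Chosen only after the result was seen were the tests of an earlier stage and of a shared array set for the LS/0B knockout pattern, the random lists set against weaker amplification, the counts without gated genes, and the search for genes that follow sets of arrays; the other tests had their bounds set before their result was seen, on alternatives added after the cells' sexes and control probe sets were known.

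Lower germ cell transcripts in LS/0B knockout cells (mean difference -0.93) were weighed against technical explanations. Uneven scaling is argued against by a median difference of 0.022 over 5083 genes detected in at least 75% of both groups, which leaves out rarer transcripts. Random lists matched on mean signal had mean differences from -0.19 to 0.29 (95%). That signal is taken over all cells, PGCs included, so the matched genes need not lie as near the floor at LS/0B as the germ cell genes. A loss of rarer transcripts by weaker amplification therefore stays open. Knockout cells had 11423 detected probe sets on average against 10600 in wild-type cells, but 6958 against 7341 at the stricter limit. The unequal sexes stay open as part of the cause: without the Xist cells of the wild type the mean difference was -0.47, between the bounds of -0.3 and -0.5 set beforehand, and these cells are also a block of replicates, 6 of 8 with Ppp2cb. An earlier stage of the knockout cells may still contribute: Hoxb1 stood 1.75 above E/MS precursors, which passed the bound of 1 set against it, but by less than the SD over cells (1.36), a condition added after the value was seen, and it is 1 gene. An array set shared with the Blimp1+ Hoxb1+ cells cannot be told apart from genotype, since the difference from these 4 cells (-0.58) has bounds that were set with the group scores already known, and loss of Blimp1, which the design names, remains an open explanation beside it.

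The genes that separate E/MB PGCs from posterior mesoderm were weighed against the array set of the mesoderm cells. Their hybridisation controls lay 1.82 above those of all other arrays, a signal outside the gene measurements. Of the 20 named genes, 20 had the same sign between EHF PGCs and Blimp1+ Hoxb1+ EHF cells, a pair with no shared cell and with controls at the common level; leaving out Prdm1, Dppa3 and Hoxb1, by which cells were chosen, 17 of 17 did, which argues against that difference as the whole cause of the signs. The EHF pair does not answer for Ppp2cb, Naa20 and Senp3, which are high on mesoderm and on Blimp1+ Hoxb1+ arrays alike. A difference between germ and somatic cells is therefore a hypothesis, and part of each size could come from the arrays, as the germ cell median was 1.99 against Blimp1+ Hoxb1+ E/MB cells in place of 2.97, although these are also other cells.

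The genes that separate E8.25 PGCs from pre-streak epiblast were weighed against sex, since Xist was in 8 of 8 epiblast cells and 0 of 8 E8.25 PGCs. Between EHF PGCs with Xist and the epiblast cells, 19 of 20 named genes had the same sign and a difference of at least 1 log2 unit, or 17 of 18 without Prdm1 and Dppa3. The epiblast cells are those by which the genes were chosen, which favours the same sign. Sex alone would leave no difference between cells with Xist, and the smallest of the 17 was 2.26, which argues against sex as the whole cause; the exception was Xist itself (-0.79). Stage, lineage and the choice of cells by Dppa3 and Prdm1 differ together here, and no other explanation was tested.

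Single cells stood apart from the others of their group in 5 of 48 groups and measures examined, where chance gives about 1 in 20. The germ cell score was 8.42 in E/MS precursor replicate 5 against 7.04 to 7.47 in the other cells of its group, and 8.10 in mesoderm replicate 5 against 7.03 to 7.51. The pluripotency score was 9.30 in EHF PGC replicate 6 against at most 8.56 in the others, and the Hox score 6.76 in E/MS precursor replicate 7 against 6.44 to 6.52. E/MS precursor replicate 6 had 8524 detected probe sets against 10597 to 11561.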

How the results depend on the processing

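Chosen only after the data were seen were the lists without gated genes, the wild-type cells without Xist, the EHF PGCs with Xist, the Blimp1+ Hoxb1+ cells in place of mesoderm, and all alternatives for the steps between stages and their genes. Of 1218 list medians recomputed, 1108 lay within the SD over cells of the value reported, 108 moved by more, and 2 that were at least 1 log2 unit or outside 95% of random lists changed sign; of 1400 values of named genes 1163 stayed, 232 moved and 5 changed sign; of 2400 member counts 1979 stayed within 1.5 times and 421 did not. For the steps, 557 of 560 list values lay within the SD over cells. Quantile normalization moved 0 of 120 medians, no floor 40 and scaling to the lys control 23. Of 140 values of named genes, quantile normalization moved 0, the mean of all probe sets 37, the higher floor 41 and no floor 82. No cell lay over 3 scaled MADs below the median of all cells in detected probe sets, so leaving such cells out gave no value. E/MS precursor replicate 6, which stood apart within its group, was not reached by this rule. No paired analysis was possible because no result comes from a test, and cells of different groups share only replicate numbers. Signal near the floor limits all values: where a group lies there, the size of a difference depends on the floor. The cause was not tested for the values that follow.

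For E8.25 PGCs against epiblast, the germ cell median was 3.82 with no floor, 2.75 from mean linear signal and 2.73 without gated genes; the pluripotency median was -0.21 from mean linear signal and -0.16 to 0.18 leaving out single cells; the mesenchymal median was -0.41 with no floor. For E/MB PGCs against mesoderm, the germ cell median was 2.40 scaled to lys, 4.03 with no floor, 1.99 with Blimp1+ Hoxb1+ cells as reference and 2.24 without gated genes; mesoderm regulators were at -0.96 with no floor, Hox genes at -0.73 scaled to lys and -0.0087 from medians over cells, and mesenchymal genes at -1.10 scaled to lys. For E/MB PGCs against Blimp1+ Hoxb1+ cells, the germ cell median was 2.14 with no floor, 2.46 with the 4 disputed cells pooled in, 1.52 without gated genes and 1.83 to 2.18 leaving out single cells; the pluripotency median was 0.27 with no floor and 0 to 0.21 leaving out single cells; with no floor mesoderm regulators were at -0.63 and mesenchymal genes at -2.29.

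For E/MB knockout cells against PGCs, the germ cell median was -2.05 scaled to lys, -1.98 with the higher floor, -1.96 from mean linear signal, -1.16 against LS/0B precursors and -2.07 without gated genes. The pluripotency median was 0.0027 scaled to lys, -0.046 with no floor, 0 from medians over cells, 0 from the mean of all probe sets and -0.39 to -0.010 leaving out single cells. Scaled to lys, mesoderm regulators were at 0.62, Hox genes at 0.54 and mesenchymal genes at 1.45; with no floor Hox genes were at 0.48 and mesenchymal genes at 2.38, and against LS/0B precursors mesenchymal genes were at 0.47. For E/MB knockout cells against mesoderm, mesoderm regulators were at -0.65 with no floor. With Blimp1+ Hoxb1+ cells in place of mesoderm, Msgn1 (0.24), Dll1 (0.73), Car3 (0.19) and Tafa5 (0.58) changed sign. Mesoderm regulators (0.016), BMP response genes (-0.011) and Firre (-0.0097) did so as well, but with almost no difference left. The cause was not tested. The SD over cells of the germ cell score was 0.82 in LS/0B and 1.21 in E/MB knockout cells with no floor, and 0.32 in E/MB PGCs scaled to lys.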

Other observations

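Both hypotheses formed after the data were seen, an earlier stage and a shared array set, stand with their tests among the results above; the values here come from the planned lists, except for the genes that follow sets of arrays, which were searched for afterwards.

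Sox17, an endoderm regulator, was detected in 8 of 8 E/MB PGCs (2.14 above LS/0B precursors), 1 of 12 E/MB knockout cells (-2.99 against PGCs) and 1 of 10 mesoderm cells, while the endoderm list as a whole had a mean difference of 0.27 between E/MB PGCs and mesoderm and -0.35 between E/MB knockout cells and PGCs. Among blood and endothelium genes, Lmo2 was higher in E/MB PGCs than in mesoderm by 2.47 and Etv2 was at -2.44, so that the list mean was -0.01. The trophoblast list had a mean of 0.48 between E8.25 PGCs and epiblast, from 1 of 7 members, Cdx2 (3.64). The neural plate list had mean scores between 6.24 and 6.37 in all groups, although its member Nes was detected in 8 of 8 cells of each PGC group, with 0 of 8 members differing by 1 log2 unit in E8.25 PGCs against epiblast.

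Histone methylation genes had a mean of -0.31 between E8.25 PGCs and epiblast, where Ehmt1, a histone H3 lysine methyltransferase, was at -3.27 and Kdm6a at -1.92; Ehmt1 was also lower in E/MB PGCs than in mesoderm (-2.49) and higher in E/MB knockout cells than in PGCs (1.87). Proliferation genes had a mean of -0.21 between E8.25 PGCs and epiblast, with Ccnd1 at -2.77, Ccne1 at -2.66 and Top2a at 1.12. Housekeeping genes had a mean of -0.11 there and of 0.49 between E/MB knockout cells and PGCs, the latter from Hprt, higher by 2.12, as 1 of 6 members. The Y linked and Xist list had a mean of -0.07 between E8.25 PGCs and epiblast, with Eif2s3y at 2.80 and Xist at -4.97.

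Beside Abca4, 5 genes were higher by at least 1 log2 unit in each of the 4 knockout and Blimp1+ Hoxb1+ groups than in each of the 6 lineage groups: Gsk3b, Igfbp4, Pard3b, Ppp2cb and Spin2c. Of 210 ways to split these 10 groups into 4 and 6, 2 gave more than 6 genes, with 25 as the highest. Mesoderm cells lay with the 4 groups in Ppp2cb (8.70), Naa20 (8.47) and Senp3 (9.51), with the lineage groups in Gsk3b (6.52 against 6.65), and between them in Abca4 (7.45). In a principal component analysis of 7221 genes, the second component held 6.28% of the variance and took mesoderm cells to between 10.2 and 101, against -24.0 to 28.2 in all other cells. Whether these arrays were processed together is not given in the sources used here.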
